A study of Mus musculus with 6 samples.

How the data were processed

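RNA-seq was performed on primary mouse osteoblasts, the bone-forming cells, that carried either a lentiviral vector encoding Mig6 or an empty lentiviral vector. Mig6 is the protein product of Errfi1 and an inhibitor of the epidermal growth factor receptor (EGFR). Per the labels' protocols, cells were exposed to vector and 6 µg/ml polybrene for 24 hours, selected with 1.5 µg/ml puromycin and differentiated for 7 days with 50 µg/ml ascorbic acid, 10 mM β-glycerophosphate and 10 µM dexamethasone. Trizol-extracted RNA was judged fit for mRNA libraries when its RNA integrity number exceeded 8.0, per the labels' protocols. The series holds 6 libraries, 3 with the empty vector (control) and 3 with the Mig6 vector (Mig6 OE), assigned from the sample titles.

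The authors deposited 1 table of the whole series with 15155 rows, all of them protein-coding genes, and 1 column of read counts per library. The read counts in that deposited table are whole numbers that were not normalized. HISAT2 was the aligner and mm10 the genome build, per the submitters' processing notes, and gene positions are on GRCm38.p6, per the file headers. The counting program, its strand setting, the annotation release and any row filter are not given in the sources used here. Each row of the table has a total of at least 10 counts and at least 5 counts in its highest library. The same table holds the authors' own comparison as a log2 fold change, a linear fold change (a ratio), a p-value and an FDR per gene, and the program behind these values is not given in the sources used here. Of the gene IDs, 99.94% were found in GENCODE mouse release M21, and 99.06% of those had the same position there. Positions below are those of the deposited table. 3 gene symbols occur on more than 1 row and were kept apart by gene ID.

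Library totals ranged from 37264210 to 50739736 counts. A floor of 3 counts corresponds to 0.0591 to 0.0805 CPM (counts scaled to library size) in these libraries. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No label says that the replicates came from separate animals, cultures or transductions, so p-values measure the spread between these libraries, which may be technical. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 1.35 to 2.97 over genes with more than 20 counts in both), so none was merged.

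Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which kept 13832 genes and left out 1323 that held 0.0141% of all counts. Library sizes were scaled with TMM, and the groups were compared with edgeR's quasi-likelihood F test (glmQLFit, glmQLFTest) over all 6 libraries without covariates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The adjusted p-values of single genes below come from this test. Standard errors (SE) of log2 fold changes were derived from the F statistic. Group values are mean CPM ± SD over 3 libraries. Counts were simulated for this comparison over 13832 genes, 200 of them changed, with the spread seen between these libraries. On these counts the test recovered 54% of genes changed by 1.1-fold, 88% at 1.5-fold, 90% at 2-fold and 100% at 4-fold. It called 14 of 13632 unchanged genes.

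30 gene lists were fixed before the data were examined, as were the tests, most alternative settings and the rule for naming genes. The lists hold 499 genes, of which 440 were tested. Each was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Of the 15 lists past the threshold, 3 also passed with an estimated correlation, namely those of interferon-stimulated, inflammatory and proliferation genes. The simulation drew its 13832 genes independently, so calls that come from correlation between genes were not tried. There the 1 list that had been raised was found and none of the others was called. Among the real libraries the same test called 3 to 8 lists in each of the 9 other splits into 3 and 3, each of which still holds unequal numbers of the 2 groups on its sides. Text on gene lists gives adjusted p-values from camera unless another test is named.

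The named genes are Errfi1, the 12 largest increases and 12 largest decreases, the 4 members of each list with the smallest p, and any tested member of the lists of ErbB receptors and ligands, ERK targets, osteoblast genes and osteoclast-regulating factors. A large change had to have an adjusted p under 0.05, no overlap between the groups, a mean of at least 16 CPM in the higher group and a symbol that is not a predicted or unnamed model. Bglap2 (2 to 11 counts per library) and Dmp1 (1 to 5 counts), named after their values were seen, fell under the low-count filter. Bglap and Bglap3 were not analysed here. Some genes that the rule covers are not reported here, though they stay in the tests and list counts.

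The alternative settings were DESeq2 size factors, upper-quartile factors, no low-count filter, a stricter filter (1 CPM in every library of a group), the DESeq2 1.42.0 Wald test on all genes of the table, limma-voom, the replicate number as a block, library sizes without Errfi1 and the 50 most abundant genes, leaving out each library in turn, an estimated correlation, and fry. After the data were examined, offsets for GC content and exon length, a test against a 1.5-fold change (glmTreat) and the DESeq2 Wald test after the low-count filter were added. GC content came from GENCODE M21 transcripts and covered 99.9% of tested genes. Figures were drawn with matplotlib 3.10.9.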

Results

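Transcript abundance was measured by RNA-seq in primary mouse osteoblasts transduced with an empty lentiviral vector (control, 3 libraries) or with a vector encoding Mig6 (Mig6 OE, 3 libraries) and differentiated for 7 days. The series addresses the role of Mig6 and EGFR signalling of osteoblasts in the subchondral bone remodelling of osteoarthritis. The control libraries held 46559042, 47818553 and 48677472 counts and the Mig6 OE libraries 37264210, 47004261 and 50739736. Log2 CPM profiles correlated at 0.997 to 0.998 within a group and at 0.988 to 0.989 between groups (Pearson's r across genes, which are not independent replicates). The first principal component of the 500 most variable genes held 87.5% of their variance and separated the groups. The median biological coefficient of variation between libraries of a group was 1.75%, so that differences of a few percent passed the test. Fold sizes are given throughout for that reason.

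Errfi1, the gene of Mig6, was higher in every Mig6 OE library than in every control library. It lies on chromosome 4 from 150853919 to 150868892 on the plus strand (GRCm38.p6; ENSMUSG00000028967). Its mean was 1115 ± 10.4 CPM (SD, n = 3) in Mig6 OE and 320.6 ± 2.55 CPM (SD, n = 3) in control cells. This 3.48-fold difference (log2 fold change 1.80, SE 0.02) had an adjusted p of 3.50e-27 by edgeR's quasi-likelihood test. The authors' deposited table gives a log2 fold change of 1.80 for the same gene. The labels do not say which species' coding sequence the vector carries, so the share of these counts that came from the vector is unknown. Control libraries held 14785 to 15160 Errfi1 counts each, and Mig6 OE libraries 42344 to 58127.

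**Figure D1:**
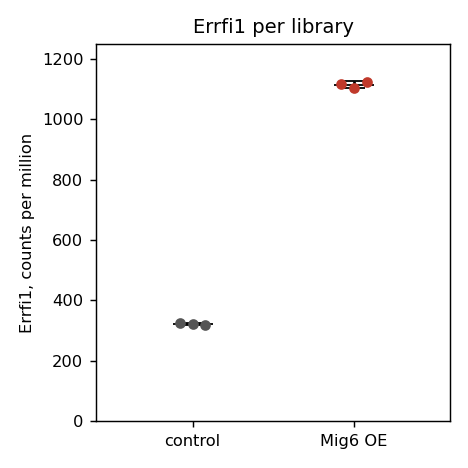
Errfi1 abundance per library. The vertical axis gives TMM-scaled CPM from 0, dots are single libraries, and bars show the mean ± SD of the 3 libraries of each group. Control libraries sit between 318.1 and 323.1 CPM and Mig6 OE libraries between 1104 and 1124 CPM.

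The main comparison asked which genes differed between Mig6 OE and control osteoblasts. Among the 12 largest decreases, Ifi208 and Ifi206, of the interferon-inducible p200 family on chromosome 1, fell 15.2-fold and 15.0-fold. H2-Q6 and H2-Q7, nonclassical class I histocompatibility genes on chromosome 17, fell 13.7-fold and 6.50-fold. Apod, which encodes the lipid carrier apolipoprotein D, fell 7.40-fold, from 354.0 ± 5.22 to 47.8 ± 2.32 CPM (SD, n = 3 each). The chemokine genes Ccl11, Cxcl10 and Cxcl9 fell 6.63-fold, 6.28-fold and 6.16-fold. Phf11b fell 6.68-fold, the antiviral gene Rsad2 6.35-fold, and the interferon-inducible GTPase genes Tgtp2 and Tgtp1 5.41-fold and 5.28-fold. The p200, H2-Q, Phf11 and Tgtp genes have close paralogs, so the division of reads among copies is uncertain.

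Among the 12 largest increases, which include Errfi1, Fhl1, a LIM-domain gene of muscle, rose 4.44-fold from 7.09 ± 0.328 to 31.4 ± 0.402 CPM (SD, n = 3 each). Ankrd1, a YAP target, rose 4.42-fold. Myh11 (smooth muscle myosin) rose 3.55-fold, Actg2 (enteric smooth muscle actin) 2.89-fold, Lmod1 (leiomodin) 2.61-fold and Acta2 (smooth muscle actin) 2.30-fold. Lrp2, an endocytic receptor gene, rose 2.59-fold and Itga6, an integrin gene, 2.34-fold. Crct1, Tinagl1 and Klhdc8a rose 2.48-fold, 2.46-fold and 2.35-fold. Adjusted p-values of these 24 genes ranged from 3.50e-27 for Errfi1 to 1.64e-13 for Lrp2 in edgeR's quasi-likelihood test.

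Of 13832 genes tested, 7024 (50.8%) changed, 3476 higher and 3548 lower in Mig6 OE. A change of at least 2-fold was seen in 484 genes, of which 127 were higher and 357 lower. The authors' deposited table lists 5483 genes at an FDR below 0.05, with 110 higher and 346 lower by at least 2-fold. All 5477 of those that were tested here were called in the same direction.

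Interferon-stimulated genes were lower in Mig6 OE. All 19 tested members of their list fell, 13 of them by at least 2-fold, with a median log2 fold change of -1.22 (adjusted p = 2.37e-17, and adjusted p = 0.0397 with an estimated correlation). The count adjusted over the list alone was also 19. Cxcl10 and Rsad2 were the members with the smallest p. Irf7, the transcription factor that amplifies type I interferon responses, fell 3.24-fold from 483.0 ± 6.59 to 149.1 ± 1.01 CPM (SD, n = 3 each). Ifit3, an antiviral effector gene, fell 3.41-fold from 830.2 ± 24.1 to 243.8 ± 4.04 CPM (SD, n = 3 each). Macrophage and other leukocyte markers did not pass as a set (2 higher and 5 lower of 14, also adjusted over the list alone; adjusted p = 0.483), and in the same libraries 8 of 11 smooth muscle and pericyte and 7 of 7 skeletal muscle markers were higher and 6 of 8 osteoclast markers were lower.

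Inflammatory cytokine, chemokine and acute phase genes were lower as well. Of 21 tested members, 18 fell, 1 rose and 2 did not pass, over all genes and adjusted over the list alone. Their median log2 fold change was -0.85 (adjusted p = 1.01e-11, and adjusted p = 0.0397 with an estimated correlation). Ccl5, a T cell chemokine gene, fell 4.43-fold and Cxcl1, a neutrophil chemokine gene, 2.29-fold. Il6 fell 2.80-fold, and Lcn2, which encodes the acute phase protein lipocalin 2, fell 2.26-fold. Markers of smooth muscle cells and pericytes (8 of 11) and of skeletal muscle (7 of 7) were higher, and those of osteoclasts (6 of 8) lower, in the same libraries.

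**Figure D2:**
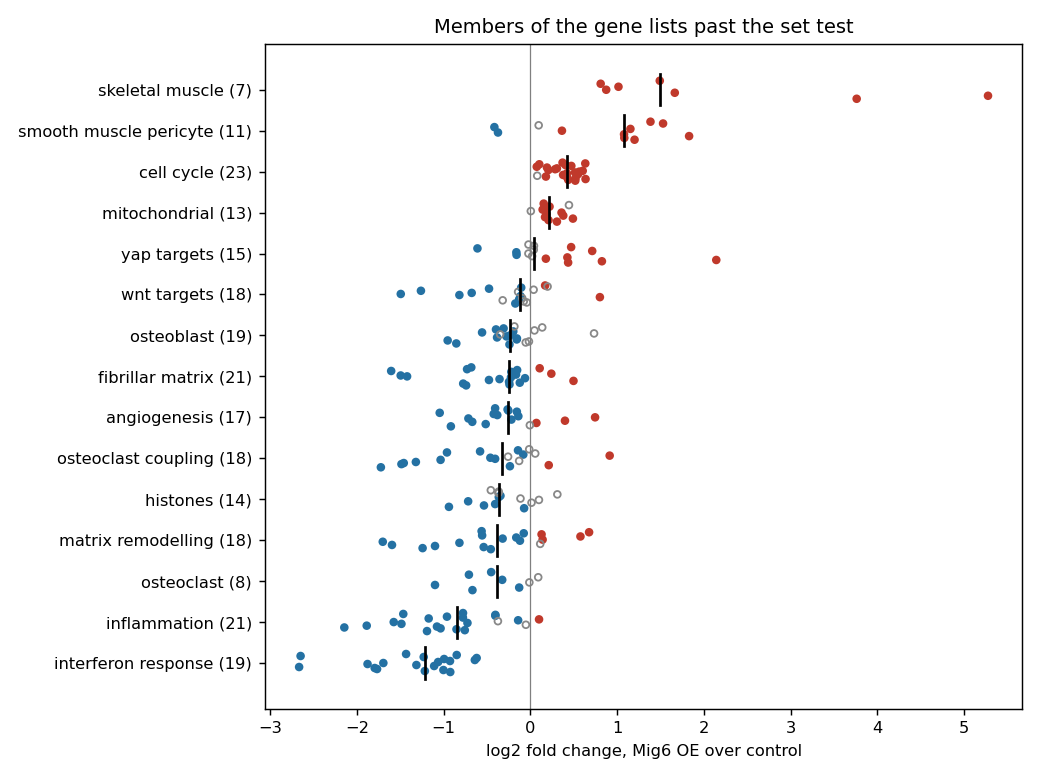
Log2 fold changes (Mig6 OE over control) of the tested members of the 15 gene lists past the set test with the preset correlation. Each dot is a gene, filled red (higher) or blue (lower) when its adjusted p was below 0.05 and open otherwise, black bars are list medians, and tested members are counted in parentheses. All 19 interferon-stimulated genes lie below 0, and 22 of 23 proliferation genes are filled red.

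Factors through which osteoblasts regulate osteoclasts, the bone-resorbing cells, were mostly lower. Tnfsf11, which encodes the osteoclast differentiation factor RANKL, fell 3.30-fold from 147.5 ± 0.494 to 44.6 ± 1.06 CPM (SD, n = 3 each; log2 fold change -1.72, SE 0.02, adjusted p = 3.11e-24 by edgeR). Tnfrsf11b, which encodes its decoy receptor osteoprotegerin, fell 1.18-fold. The number of Tnfsf11 counts per Tnfrsf11b count was 1.95 ± 0.0433 in control and 0.694 ± 0.0138 in Mig6 OE libraries (SD, n = 3 each), without overlap. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The interleukin-6 family genes Il6, Il11 and Lif fell 2.80-fold, 2.75-fold and 2.50-fold. Il6 also belongs to the list of inflammatory genes above, so the results of these lists are not independent. Ccl2 (monocyte chemokine) fell 2.05-fold and Ptgs2 (cyclooxygenase 2) 1.95-fold, from 2183 ± 26.5 to 1121 ± 36.0 CPM (SD, n = 3 each). Sema3a, a semaphorin that restrains osteoclast formation, rose 1.88-fold, and Csf1, the macrophage colony-stimulating factor, rose 1.16-fold.

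Over the whole list of osteoclast-regulating factors, 12 of 18 tested members fell, 2 rose and 4 did not pass, and 13 fell when adjusted over the list alone. The median log2 fold change was -0.33 (adjusted p = 1.29e-04, and adjusted p = 0.0588 with an estimated correlation). Wnt5a (-0.46), Cxcl12 (-0.41) and Il1rn (-0.58) also fell on the log2 scale. Of 8 osteoclast markers tested, 6 fell and none rose, over all genes and adjusted over the list alone (adjusted p = 0.00916, and adjusted p = 0.219 with an estimated correlation). Among these, Itgb3 (integrin β3) fell 1.63-fold, Tcirg1 (a proton pump subunit) 1.37-fold, Mmp9 2.14-fold and Acp5 (tartrate-resistant acid phosphatase) 1.59-fold. Acp5 and Mmp9 stood at only 4.46 and 4.37 CPM in control cells. Smooth muscle and pericyte markers (8 of 11) and skeletal muscle markers (7 of 7) were higher alongside.

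**Figure D3:**
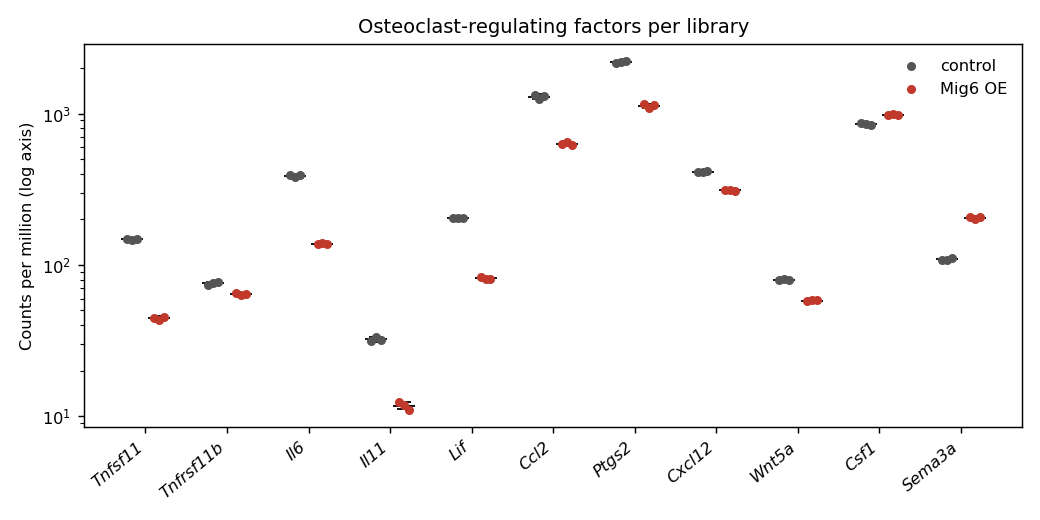
Abundance of 11 osteoclast-regulating factors per library. The logarithmic vertical axis gives CPM, dots are single libraries (grey control, red Mig6 OE), and bars show the mean ± SD of 3 libraries. Tnfsf11 drops from 147.5 to 44.6 CPM, while Sema3a and Csf1 lie higher in Mig6 OE.

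Matrix proteases and their inhibitors fell in 13 of 18 tested members and rose in 4 (5 rose when adjusted over the list alone, where 13 fell). Mmp13, the osteoblast collagenase, fell 3.25-fold from 1974 ± 5.93 to 606.6 ± 5.24 CPM (SD, n = 3 each), and Mmp3 (stromelysin 1) fell 2.37-fold. Mmp2 fell 1.37-fold, and the protease inhibitor gene Timp1 fell 1.47-fold. The list's adjusted p was 0.0021, and adjusted p = 0.117 with an estimated correlation. The osteoclast markers (6 of 8 lower, Mmp9 on both lists), the smooth muscle and pericyte markers (8 of 11 higher) and the skeletal muscle markers (7 of 7 higher) differed in the same libraries.

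Genes of the osteoblast programme were lower, by smaller factors. The list holds 24 genes, of which 19 were tested. Of these 19, 12 fell, none rose and 7 did not pass, over all genes and adjusted over the list alone. Bglap2 (2 to 11 counts per library) and Dmp1 (1 to 5) were too low to test. The median log2 fold change was -0.24 (adjusted p = 6.65e-04, and adjusted p = 0.0757 with an estimated correlation). Alpl, the alkaline phosphatase of mineralising cells, fell 1.94-fold from 20.3 ± 0.758 to 10.4 ± 0.729 CPM (SD, n = 3 each). Sp7 (osterix), a transcription factor of osteoblast commitment, fell 1.81-fold, Pth1r (parathyroid hormone receptor) 1.47-fold and Runx2 1.18-fold. The abundant matrix genes Spp1 (osteopontin), Sparc (osteonectin), Col1a1 and Col1a2 fell 1.21-fold, 1.18-fold, 1.12-fold and 1.11-fold. Ibsp (bone sialoprotein; log2 fold change -0.38, adjusted p = 0.0399 by edgeR) lost its call with the DESeq2 Wald test (adjusted p = 0.148). It also lost it without control replicate 2 (adjusted p = 0.160 by edgeR) or 3 (0.0683) or Mig6 OE replicate 1 (0.109) or 3 (0.112), and over all alternatives the adjusted p ranged from 0.0251 to 0.160. In the same libraries 8 of 11 smooth muscle and pericyte markers, 7 of 7 skeletal muscle markers and 22 of 23 proliferation genes were higher, and 6 of 8 osteoclast markers were lower. Late osteoblast and osteocyte genes moved both ways (3 higher and 3 lower of 7, also adjusted over the list alone; adjusted p = 0.800). Within that list Ptprz1 rose 2.18-fold and Cd44 1.11-fold, and Pdpn fell 1.18-fold.

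Fibrillar collagens and matrix assembly genes fell in 18 of 21 members and rose in 3, over all genes and adjusted over the list alone (median log2 fold change -0.24; adjusted p = 5.37e-06, and adjusted p = 0.0588 with an estimated correlation). The proteoglycan genes Lum and Dcn fell 2.82-fold and 2.68-fold, Dcn from 1886 ± 15.0 to 703.7 ± 5.45 CPM (SD, n = 3 each). Col3a1 fell 1.67-fold and Tnc (tenascin C) 1.66-fold. Secreted angiogenic factors fell in 13 of 17 members and rose in 3, over all genes and adjusted over the list alone (adjusted p = 4.24e-04, and adjusted p = 0.0588 with an estimated correlation). Slit3 fell 2.06-fold, Vegfa 1.89-fold and Angpt1 1.64-fold. Neurotrophins and axon guidance cues fell in 9 and rose in 4 of 14 members, over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.0614). It passed with upper-quartile factors (adjusted p = 0.0357), limma-voom (0.0406) and fry (3.31e-06), and not with an estimated correlation (0.184). Over the alternatives that kept camera with the preset correlation, its adjusted p ranged from 0.0357 to 0.153. Slit2 fell 1.84-fold and Sema3e rose 1.99-fold. Alongside these matrix and secreted-factor genes, 8 of 11 smooth muscle and pericyte and 7 of 7 skeletal muscle markers were higher and 6 of 8 osteoclast markers lower.

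Wnt targets and regulators fell in 9 of 18 members and rose in 2, over all genes and adjusted over the list alone (adjusted p = 0.0200, and adjusted p = 0.117 with an estimated correlation). The 4 members with the smallest p encode secreted Wnt antagonists or modulators: Sfrp2, Wif1 and Sfrp1 fell 2.82-fold, 2.40-fold and 1.76-fold, and Dkk2 rose 1.74-fold. Higher smooth muscle and pericyte (8 of 11) and skeletal muscle markers (7 of 7) and lower osteoclast markers (6 of 8) were seen in the same libraries. BMP and TGF-β targets and regulators moved both ways (5 higher and 8 lower of 20, also adjusted over the list alone; adjusted p = 0.800), and their median (0.0039) and mean (-0.08) log2 fold changes differed in sign. Grem1, a secreted BMP antagonist gene, fell 1.86-fold and Tgfbi 1.76-fold, while Ccn2 rose 1.77-fold.

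ErbB receptors and their ligands did not pass as a set. Of 13 tested, 4 fell, 1 rose and 8 did not pass, over all genes and adjusted over the list alone (adjusted p = 0.587). Egfr fell by 0.14 on the log2 scale, from 102.0 ± 2.23 to 92.6 ± 1.62 CPM (SD, n = 3 each), and Erbb2 stood at 24.5 ± 0.210 and 24.0 ± 0.250 CPM (SD, n = 3 each; adjusted p = 0.442 by edgeR). Ereg (epiregulin), the most abundant ligand of the list, fell 1.46-fold. Btc (betacellulin) and Areg (amphiregulin) fell 2.11-fold and 1.77-fold from 2.88 and 1.33 CPM. Hbegf rose 1.52-fold, from 23.8 ± 0.954 to 36.2 ± 0.521 CPM (SD, n = 3 each).

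Genes induced by ERK, a kinase downstream of EGFR, moved both ways. Of 23 tested, 13 fell, 5 rose and 5 did not pass, over all genes and adjusted over the list alone, and the set test did not pass (median log2 fold change -0.11, adjusted p = 0.0856). The feedback inhibitor genes Spry2 and Spry4 fell 1.43-fold and 1.25-fold. The transcription factor genes Etv1, Fosl1 and Fos fell 1.42-fold, 1.38-fold and 1.30-fold. Dusp4 and Dusp5, which encode phosphatases that act on mitogen-activated kinases, both rose 1.44-fold. Ccnd1 (cyclin D1) rose 1.34-fold, from 492.2 ± 6.46 to 657.1 ± 7.28 CPM (SD, n = 3 each).

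Proliferation genes were higher in Mig6 OE by modest factors. Of 23 tested, 22 rose and none fell (23 rose when adjusted over the list alone). The median log2 fold change was 0.42 (adjusted p = 6.28e-11, and adjusted p = 0.0397 with an estimated correlation). Ccnb1 (cyclin B1) rose 1.55-fold, Mki67 1.43-fold, Rrm2 1.39-fold and Top2a 1.35-fold. Smooth muscle and pericyte (8 of 11) and skeletal muscle markers (7 of 7) were higher and osteoclast markers (6 of 8) lower in the same libraries. Mitochondrially encoded genes rose in 11 of 13 members and fell in none (12 rose when adjusted over the list alone; median log2 fold change 0.21, adjusted p = 1.88e-04, and adjusted p = 0.0588 with an estimated correlation). They took 2.77 to 2.83% of counts in Mig6 OE and 2.42 to 2.52% in control libraries. Histone genes, most of whose transcripts lack a poly(A) tail, fell in 7 of 14 members and rose in none, over all genes and adjusted over the list alone (adjusted p = 0.0394, and adjusted p = 0.158 with an estimated correlation). That call also ended without control replicate 1 (adjusted p = 0.0635) or Mig6 OE replicate 2 (0.0564), with the stricter filter (0.0559) and with limma-voom (0.0544). Over the alternatives that kept camera with the preset correlation, the adjusted p ranged from 0.0175 to 0.0635. With fry it was 1.34e-04.

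Smooth muscle and pericyte markers were higher in 8 of 11 members, 7 of them by at least 2-fold, and lower in 2 (9 rose and 2 fell when adjusted over the list alone). Their median log2 fold change was 1.08 (adjusted p = 1.01e-04, and adjusted p = 0.0588 with an estimated correlation). Acta2 rose from 1158 ± 12.8 to 2662 ± 23.1 CPM (SD, n = 3 each), Tagln 2.12-fold and Cnn1 2.11-fold. All 7 tested skeletal muscle markers rose, over all genes and adjusted over the list alone, at low abundance (adjusted p = 4.24e-04, and adjusted p = 0.0588 with an estimated correlation). Acta1 rose 3.17-fold to 8.15 ± 0.337 CPM (SD, n = 3). Myh3, the embryonic myosin gene, held 10 counts over the 3 control libraries and 138 over the 3 Mig6 OE libraries, and Myh8 held 1 and 52 counts, a ratio of 55.1 (95% exact counting interval 9.46 to 2218). The Myh8 ratio was 37.2 and 36.4 without control replicates 1 and 3. Its only control count was in control replicate 2, without which Myh8 was at least 12.2-fold higher in Mig6 OE (against 3 counts over the control group). YAP/TAZ targets rose in 7 and fell in 3 of 15 members, over all genes and adjusted over the list alone, with a median log2 fold change of 0.04 (adjusted p = 0.0325, and adjusted p = 0.219 with an estimated correlation). The YAP/TAZ call also ended without control replicate 1 (adjusted p = 0.0556). Over the alternatives that kept camera with the preset correlation, the adjusted p ranged from 0.00754 to 0.0556, and with fry it was 8.28e-06. Crim1 rose 1.64-fold and Ccn1 1.35-fold.

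The remaining lists did not pass the set test. Adipocyte markers moved both ways (2 higher and 2 lower of 7; 4 and 2 adjusted over the list alone; adjusted p = 0.970), as did chondrocyte markers (3 higher and 6 lower of 15; 4 and 6 adjusted over the list alone; adjusted p = 0.894). For both lists the median log2 fold change (0.13 each) was positive and the direction of the set test was down. Sox5 and Dgat2 fell 1.96-fold and 1.48-fold, and Col2a1 rose 1.33-fold. Endothelial markers were lower in 2 of 6 and higher in none (1 lower adjusted over the list alone; adjusted p = 0.511). Glucocorticoid-induced genes fell in 7 and rose in 3 of 12 members (8 and 3 adjusted over the list alone; adjusted p = 0.215), with Mt2 1.46-fold lower and Pdk4 1.69-fold higher. Stress-response genes fell in 10 and rose in 5 of 18 (adjusted p = 0.483), with Trib3 and Ddit3 1.84-fold and 1.83-fold lower. Glycolytic genes fell in 7 and rose in 5 of 17 (adjusted p = 0.483), with Pfkfb3 1.53-fold lower. Targets of p53 rose in 3 and fell in 3 of 15 (adjusted p = 0.581), with Perp 1.81-fold higher and Cdkn1a 1.14-fold lower. Sterol synthesis genes rose in 4 and fell in 4 of 19 (adjusted p = 0.800), and their median (-0.02) and mean (0.01) log2 fold changes differed in sign, as did those of the p53 targets (-0.0094 and 0.07). Immediate early and heat shock genes that respond to handling rose in 3 and fell in 6 of 12 (adjusted p = 0.407). For these last 5 lists, from the stress-response to the handling genes, the counts adjusted over the list alone were the same.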

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

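Only the offsets for GC content and exon length, the test against a 1.5-fold change and the DESeq2 run on filtered genes were chosen after the results were seen. The number of changed genes was 7024, and across normalizations, filters, tools and left-out libraries it ranged from 5710 (DESeq2 Wald test on all 15155 genes, and 5765 on the 13832 that pass the filter) to 7436 (GC content and exon length offsets). The number changed by at least 2-fold was 484 and ranged from 340 (stricter filter) to 580 (no filter). Leaving out single libraries gave 6268 to 6784 changed genes, 499 to 520 changed by at least 2-fold, 13 to 15 lists past the threshold, and an Errfi1 log2 fold change of 1.79 to 1.81. Against a minimum change of 1.5-fold (glmTreat) 652 genes passed, 154 higher and 498 lower, since that test asks for a larger change. Upper-quartile scaling gave 4007 higher and 3154 lower genes, with a median log2 fold change of all genes of 0.018. The number of lists past the threshold was 15 with the preset correlation, 3 with an estimated correlation (the cause was not tested) and 28 with fry, which does not compare a list with other genes. Higher estimates do not account for every loss. The skeletal muscle (-0.0807), angiogenic (-0.0294) and mitochondrial (-0.0310) lists lost their call with estimates below the preset 0.01. Other lists lost it with higher estimates, as the osteoclast markers did (0.199). A lost call is therefore not by itself a sign of correlation between genes. For the skeletal muscle list the unadjusted camera p rose from 1.16e-04 to 0.0165 despite its lower estimate. The same-numbered libraries did not deviate together (correlations of -0.229, -0.156 and 0.0557 across 9631 genes). These values gave no sign of pairing by number, but a small shared effect could be missed, and the labels do not say. With the replicate number as a block, 6688 genes changed, 481 of them by at least 2-fold, and 15 lists passed.

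Some lists and genes that had not passed turned direction, and the cause was not tested. The adipocyte list turned with the replicate block (adjusted p = 0.937) and without control replicate 1 or any Mig6 OE replicate, with adjusted p-values of 0.864 to 0.997 over the left-out libraries. The chondrocyte list turned without Mig6 OE replicate 3 (range over left-out libraries 0.774 to 0.993) and with GC content and exon length offsets (0.978), and BMP and TGF-β targets turned with fry (0.00168). Among single genes, upper-quartile factors turned the log2 fold change of Cthrc1 (0.00449). Leaving out single libraries turned Egf (-0.226 to 0.163), Erbb3 (-0.216 to 0.0551), Dusp6 (-0.0313 to 0.00492) and Fosb (-0.0832 to 0.109). At this depth Myh3 and Myh8 held 10 and 1 counts over the control libraries, which limits the precision of their folds.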

Other observations

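The tests of explanations below were chosen after the results were seen, except those on other splits of the libraries. A scan of all 229 gene families with at least 8 tested members sharing a symbol stem described further groups. By camera with the preset correlation 20 families passed, 10 higher and 10 lower, and with an estimated correlation 0 passed (16 had an unadjusted p below 0.05). All 9 guanylate-binding protein genes (Gbp, interferon-inducible GTPases) fell, with a median log2 fold change of -1.90 (adjusted p = 8.61e-08, and adjusted p = 0.250 with an estimated correlation). Class I and other H2 histocompatibility genes fell in 11 of 15 members and rose in 1 (median -1.21, adjusted p = 2.76e-05, and adjusted p = 0.640 with an estimated correlation). The Rpl and Rps stems also passed, and were tested again without the kinase, binding protein, pseudogene and retrogene symbols they hold (3 and 13 left out). Of the ribosomal protein genes that stayed, 43 of 47 Rpl and 29 of 31 Rps genes rose and 1 of each fell (median log2 fold changes 0.15 and 0.18). For these sets camera gave adjusted p = 6.57e-10 and 9.73e-09 over the 2 sets, and adjusted p = 0.203 each with an estimated correlation. Their medians were 0.11 and 0.14 after GC content and exon length offsets. The augmin genes (Haus, spindle assembly) rose in 7 of 8 members (median 0.24, adjusted p = 0.0143, and adjusted p = 0.640 with an estimated correlation).

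The interferon list fell with a median log2 fold change of -1.22, and fewer leukocytes are argued against as the cause, since the 14 macrophage and leukocyte markers tested, none of them on another list, had a median of -0.0797 (quartiles -0.26 and 0.04). Osteoclast markers, of the related myeloid lineage, did fall (6 of 8, median -0.39, adjusted p = 0.00916, and adjusted p = 0.219 with an estimated correlation), and a part played by fewer cells of that lineage was not tested. A genetic or mapping difference limited to the multi-copy interferon loci of chromosomes 1 and 17 is also argued against for the list's fall. This follows from the list's make-up rather than from a test, since 18 of its 19 tested members lie on other chromosomes. These 18 members all fell, with a median of -1.22. They cannot decide whether such a difference affects Ifi208, Ifi206, H2-Q6 and H2-Q7, which lie on chromosomes 1 and 17. For these genes such a difference stays open. The interferon gene Ifnb1, picked after its values were seen, fell as well (61, 56 and 74 counts in control, 13, 18 and 7 in Mig6 OE libraries; log2 fold change -2.29). An effect of Mig6 on interferon production and a different exposure to the 2 vector preparations may each give that value and cannot be told apart, because vector and group are the same variable.

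The higher contractile genes form another pattern. Skeletal muscle cells are argued against as the cause of the Acta2 rise. The highest skeletal muscle marker reached 8.15 CPM in Mig6 OE, while Acta2 rose by 1504 CPM. For smooth muscle genes of low abundance this comparison cannot decide, as Myh11 rose only from 5.02 to 17.9 CPM. A larger share of smooth muscle cells or pericytes cannot be told apart from a change within the osteoblasts. The 6 contractile members of that list had a median log2 fold change of 1.29, and the 5 others had a median of 0.0950 but ranged from -0.42 to 1.15. A shared rise of YAP/TAZ targets is a hypothesis that stays open (adjusted p = 0.219 with an estimated correlation).

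Of the tested genes, 50.8% changed. A GC content or exon length trend is argued against as the cause, since 7436 genes (3479 higher and 3957 lower) were called after both were removed. Of the 484 genes changed by at least 2-fold, 471 stayed. The overlap of the smaller changes is not given here. Replicates drawn from 1 culture or 1 transduction per group could make any difference between those cultures pass the test, and the median biological coefficient of variation of 1.75% leaves this open, as no library of a second culture is identified. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split was the only 1 to reach 7024 changed genes, 484 changed by at least 2-fold or 15 lists. Each of the other 9 splits gave 0 genes and 0 genes by edgeR but 3 to 8 lists by camera with the preset correlation, and at an unadjusted p below 0.05 they gave at most 238 genes, against 7728. Both groups stand on each side of these 9 splits, so the group difference adds to their spread. Their counts therefore do not show what libraries without a difference would give.

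2 genes were singled out after their values were seen. Csprs, a multi-copy gene placed on an unlocalised scaffold, held 181 counts over the control libraries and 2 over the Mig6 OE libraries, a ratio of 85.4 (95% exact counting interval 23.3 to 711). The Csprs ratio was 55.7 and 53.3 without Mig6 OE replicates 2 and 3, and without replicate 1, which held both Mig6 OE counts, Csprs was at least 41.2-fold lower in Mig6 OE (against 3 counts over the group). Entpd4b, which has close paralogs, held 214 counts in control replicate 2 and 270 in Mig6 OE replicate 3 but 14 to 26 in each of the other 4 libraries.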
